A study of Homo sapiens with 9 samples.

How the data were processed

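Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA crosslinked to a protein of interest, and sites of binding appear as peaks of reads over background. Per the labels, 9 samples were prepared from MCF7, an oestrogen receptor-positive human breast cancer cell line, and from FULVR, its derivative that is resistant to the oestrogen receptor degrader fulvestrant. VGLL1, a transcriptional cofactor without a DNA-binding domain of its own, was precipitated in 3 FULVR samples. TEAD4, a DNA-binding transcription factor and partner of VGLL1, was precipitated in 2 FULVR and in 2 MCF7 samples, and each line had 1 input sample without antibody. MCF7 was grown with 10 nM estradiol and FULVR with 100 nM fulvestrant, both in medium with 10% serum, so the cell line and the culture supplement changed together. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, chromatin was sonicated and libraries were made with a standard DNA kit.

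The deposited data used here were 3 peak lists, for TEAD4 in FULVR, TEAD4 in MCF7 and VGLL1 in FULVR. The submitters' processing notes name Bowtie2, SAMtools and MACS2 and the human genome build hg19, without versions or roles. Ends on chromosome 1 reached 249168738, and all coordinates are given in hg19, counted from 1. Each list gives positions and 1 whole-number score per peak, as deposited by the authors. The lowest score in every list was 20, which is 10 times the negative base-10 logarithm of 0.01, the q value in the names of the deposited lists. The score was therefore read as 10 times the negative log10 of the q value, the form in which MACS2 writes its BED score; no source used here states the unit in words. Whether replicates were pooled, merged or represented by 1 library was not given in the sources used here. The names of the 29930 VGLL1 peaks carried 1 sample tag and numbers up to 39516, so not every numbered peak is in the list. Read depth, summits and per-replicate values were not used here, since the lists hold none, and no error between replicates can be attached to any value. A score depends on depth and on the control as well as on occupancy, so scores were tested only within a list. Where a site's scores from several lists are given, each describes the site in its own list and they are not on a common scale. Intervals and p-values below treat peaks as independent and describe these lists, not the spread between cultures.

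The VGLL1 list uses carriage returns alone as line ends, and 2 blank rows at the end of each TEAD4 list were left out. Peaks were called overlapping when they shared at least 1 bp. No list contained peaks that overlapped each other. Overlap was tested one-sided against 1000 random rotations of 1 list along each chromosome, within the span covered by the 3 lists, which keeps peak widths, numbers and clustering. In the comparison of the cell lines the FULVR TEAD4 peaks were rotated, and in the comparison with VGLL1 the VGLL1 peaks. The rotations do not account for the accessible part of the genome. Classes of peaks were compared with two-sided Fisher's exact tests, and with a Cochran-Mantel-Haenszel odds ratio over 5 score classes of equal size. Scores of classes within a list were compared with two-sided permutation tests of the rank sum with 100000 resamples. Shares carry 95% Wilson intervals, which cover counting error only. Benjamini-Hochberg adjustment was made over the 8 main tests. The highest-scoring 10 peaks of each of 5 classes were the peaks to be named: FULVR TEAD4 peaks with and without MCF7 TEAD4 overlap, MCF7 TEAD4 peaks without FULVR TEAD4 overlap, and VGLL1 peaks with and without TEAD4 overlap. These main tests, most of their alternatives and the naming rule were fixed before the data were examined.

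The plan also held tests of gene locations, sequence motifs and 15 gene lists, with VGLL1, TEAD4, EGFR and ESR1 always to be named. These were not run, because the gene table at hand uses build GRCh38 and coordinates were not converted between builds. Peaks are accordingly identified by position, and no peak is assigned to a gene.

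Dense TEAD4 clusters were defined after the data were seen, as runs of at least 20 peaks of 1 TEAD4 list in which neighbours lay within 10 kb. Regional counts of the TEAD4 lists in windows of 5 Mb, also chosen after seeing the data, were compared with two-sided Fisher's exact tests, adjusted over 595 windows; chromosome Y was left out. Ratios of shares in these windows carry 95% log-normal intervals. On simulated data, the rotation test with 200 rotations called 7% of 100 unrelated list pairs at the 0.05 level, and an overlap of 40% planted in an MCF7-sized list was recovered as 40.3%. The rank test with 200 resamples called 4% of 100 unrelated classifications of the 20465 FULVR TEAD4 peaks. The unrelated lists were made by rotation and the classifications at random, as the tests themselves assume. These rates therefore do not cover lists that share accessible DNA. A planted odds ratio of 2 was recovered as 2.05 in the stratified test, 0 of 20 shuffled list pairs gave a called window, and a window given 60 extra peaks was called in 20 of 20 sets. The shuffle moved list labels over single peaks, as the window test itself assumes. It therefore does not give the rate of false calls where peaks lie in clusters. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.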

Results

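Binding sites of TEAD4 were mapped in parental MCF7 cells and in fulvestrant-resistant FULVR cells, and sites of VGLL1 in FULVR cells. The TEAD4 list of FULVR held 20465 peaks, that of MCF7 6826 peaks and the VGLL1 list 29930 peaks. The labels give 2, 2 and 3 samples for these, but how many libraries each list rests on is not stated, and the names in the VGLL1 list carry 1 sample tag. Median peak widths were 296 bp, 330 bp and 414 bp, and the peaks covered 6.75 Mb, 2.60 Mb and 14.0 Mb in the same order. Median scores were 98, 92 and 183, with maxima of 3810, 2271 and 5061. The lists carry neither read depth nor replicate values, so their lengths, with 3.00 times as many TEAD4 peaks in FULVR as in MCF7, were not tested as a difference between the lines.

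The first comparison concerned how TEAD4 occupancy in the resistant line relates to that in the parental line. Most TEAD4 peaks of MCF7 were found again in FULVR, whereas most FULVR peaks had no counterpart in the MCF7 list. Of the MCF7 peaks, 5077 of 6826 (74.4%, 95% interval 73.3 to 75.4) were overlapped by a FULVR TEAD4 peak, and 1749 were not. Of the FULVR peaks, 5162 of 20465 (25.2%, 24.6 to 25.8) were overlapped by an MCF7 peak, leaving 15303 listed in FULVR without one. The midpoints of FULVR peaks with an MCF7 counterpart lay a median of 36.5 bp from the nearest MCF7 midpoint, a distance that the overlap rule itself limits.

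The overlap of the MCF7 list was 111 times its mean of 0.667% over 1000 rotations, and the highest rotation gave 2.53% (one-sided permutation p = 0.001, the smallest that 1000 rotations can give; adjusted p = 0.00114). FULVR peaks shared with MCF7 had a median score of 202, against 83 for the unshared ones. A shared peak scored above an unshared one with probability 0.72 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 2.67e-05). In the highest-scoring 10% of the MCF7 list 98.1% of peaks were overlapped by a FULVR peak, against 45.1% in the lowest 10%. In the FULVR list the share overlapped by MCF7 went from 11.3% in the lowest 10% to 63.8% in the highest. When the FULVR list was limited to its 6826 highest-scoring peaks, as many as the MCF7 list holds, 44.8% of MCF7 and 44.5% of FULVR peaks were shared. This changed the length and the scores of the FULVR list together.

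**Figure D1:**
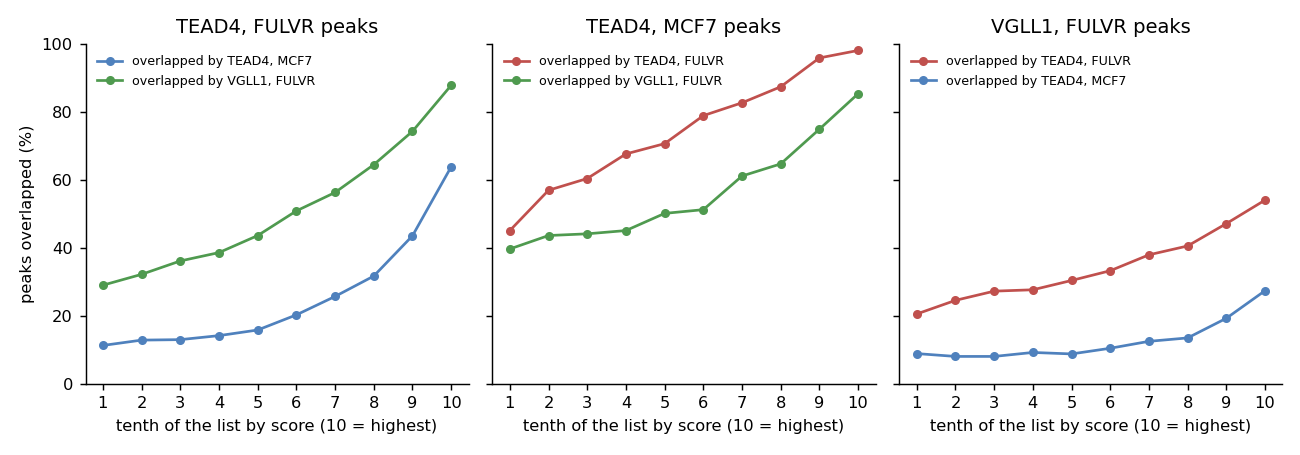
Percentage of peaks (y axis) overlapped by each other list, in 10 classes of equal size ranked on the list's score (x axis, 10 = highest), for the TEAD4 peaks of FULVR, the TEAD4 peaks of MCF7 and the VGLL1 peaks of FULVR. The FULVR TEAD4 overlap of MCF7 TEAD4 peaks reached 98.1% in the highest class, whereas that of VGLL1 peaks reached 54.1%.

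The 10 strongest shared TEAD4 sites were the 10 strongest of the whole FULVR list, with FULVR scores between 2616 and 3810. The strongest lay at chromosome 1, 19378730 to 19379478, with a score of 3810 in FULVR and 1065 in MCF7. It was followed by chromosome 7, 46184744 to 46185520 (3394 and 438), and chromosome 2, 144502567 to 144503150 (2965 and 545). All 10 were also overlapped by a VGLL1 peak, as were 87.8% of the highest-scoring 10% of the FULVR list. The strongest FULVR TEAD4 site without an MCF7 peak, at chromosome 16, 73638977 to 73639918, had a score of 2451 and ranked 14 in its list. Its nearest MCF7 midpoint was 574 kb away. The next were at chromosome 2, 227342587 to 227343398, with a score of 2409, and chromosome 8, 40930553 to 40931040, with a score of 2074. The 10 strongest such sites scored at least 1632, and all 10 carried a VGLL1 peak. TEAD4 sites of MCF7 without a FULVR peak were weaker within their own list. The strongest, at chromosome 10, 9080297 to 9080704, had a score of 788 and ranked 133, and of the 10 strongest 2 carried a VGLL1 peak.

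Relative to VGLL1 peaks, TEAD4 peaks of both lines took larger shares on chromosomes 17 and 20. Chromosome 20 held 7.30% of FULVR and 8.94% of MCF7 TEAD4 peaks but 3.27% of VGLL1 peaks. Chromosome 17 held 6.84%, 8.29% and 4.44%. Part of these peaks lay in short stretches, which were singled out after the data were seen. In FULVR the stretches held 612 of 1494 TEAD4 peaks on chromosome 20 and 166 of 1399 on chromosome 17. The stretch with the most peaks, at chromosome 20, 55665768 to 55854985, carried 150 FULVR TEAD4, 90 MCF7 TEAD4 and 17 VGLL1 peaks within 189 kb. A stretch of 187 kb at chromosome 17, 59389352 to 59575971, carried 118, 60 and 17. In all, 16 dense stretches covering 1.68 Mb held 843 FULVR TEAD4 peaks (4.12% of the list), 371 MCF7 TEAD4 peaks (5.44%) and 146 VGLL1 peaks (0.488%). The stretches were chosen on TEAD4 counts alone, so an excess of TEAD4 over VGLL1 inside them is built in. Of these stretches 10 were on chromosome 20, 3 on chromosome 17, 2 on chromosome 2 and 1 on chromosome 21. FULVR TEAD4 peaks inside them had a median score of 54, against 102 outside. Without these stretches the share of MCF7 TEAD4 peaks found again in FULVR was 73.7%.

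**Figure D2:**
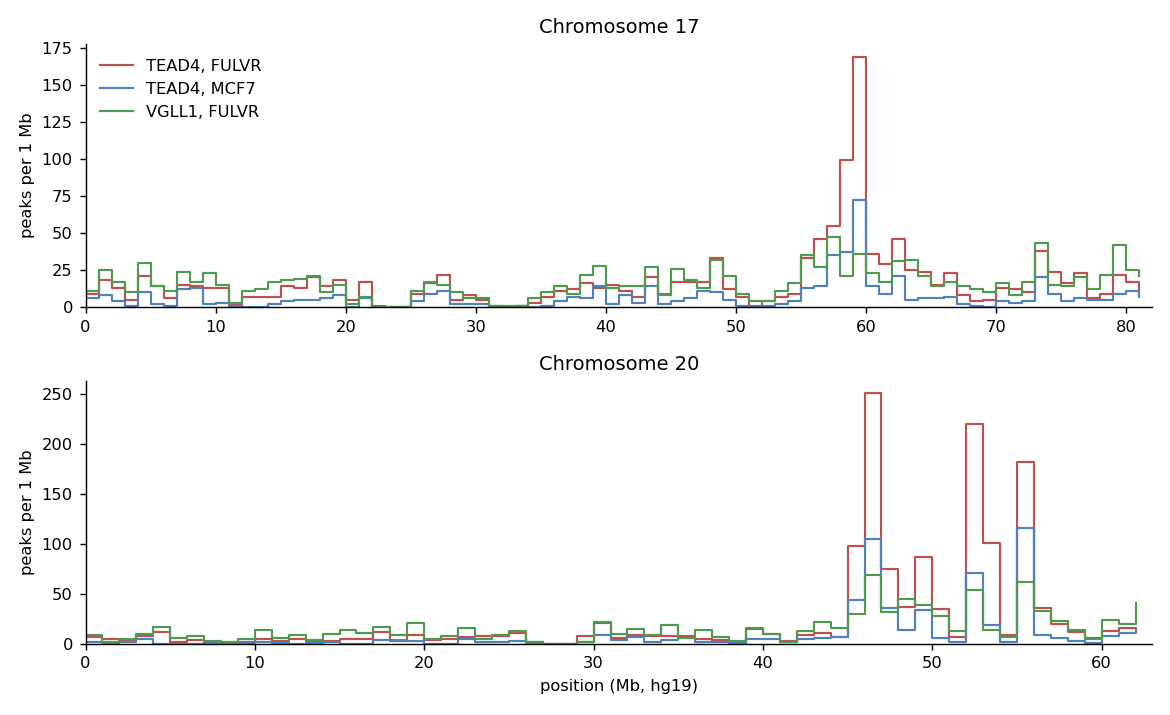
Number of peaks per 1 Mb (y axis) along chromosomes 17 and 20 (x axis, position in Mb, hg19) for the 3 lists. The TEAD4 peaks of FULVR rise to 169 in the megabase that starts at 59 Mb on chromosome 17 and to 251 in the megabase that starts at 46 Mb on chromosome 20, where VGLL1 has 36 and 69. These megabases were picked for their TEAD4 counts.

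The next comparison addressed whether VGLL1 and TEAD4 occupy the same sites in FULVR cells. About as many TEAD4 sites carried VGLL1 as did not: 10507 of 20465 TEAD4 peaks (51.3%, 95% interval 50.7 to 52.0) were overlapped by a VGLL1 peak. VGLL1 was listed at many further sites, and 10279 of its 29930 peaks (34.3%, 33.8 to 34.9) were overlapped by a FULVR TEAD4 peak, while 19651 were not. Where both were listed, their midpoints lay a median of 52 bp apart, and 75.1% lay within 100 bp. Only overlapping peaks were measured, so the overlap rule itself limits this distance, and no random expectation was computed for it. The overlap of the TEAD4 list was 57.3 times its mean of 0.896% under rotation, with a highest rotation of 2.95% (one-sided permutation p = 0.001, the smallest possible; adjusted p = 0.00114).

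Stronger TEAD4 sites carried VGLL1 more often, from 29.0% in the lowest 10% of TEAD4 scores to 87.8% in the highest. VGLL1 peaks with TEAD4 had a median score of 270, against 152 without it, and scored higher with probability 0.63 (two-sided permutation p = 1e-05, the smallest possible; adjusted p = 2.67e-05). In the highest 10% of the VGLL1 list 54.1% of peaks were overlapped by FULVR TEAD4, against 20.5% in the lowest. With both lists limited to their 6826 highest-scoring peaks, 30.96% of TEAD4 peaks were overlapped by VGLL1. This limit changed the lengths and the scores of both lists together, and it left out the weaker VGLL1 peaks at strong TEAD4 sites.

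The strongest VGLL1 peak overlapped by TEAD4, at chromosome 9, 3740564 to 3741751, had a score of 5061, and its TEAD4 peak in FULVR had a score of 140 in the TEAD4 list. The next lay at chromosome 17, 77110007 to 77111565, with scores of 4743 for VGLL1 and 126 for TEAD4, and at chromosome 1, 53572879 to 53573971, with 4586 and 672. Over the 10 strongest VGLL1 peaks with TEAD4, the TEAD4 scores ran from 61 to 1433. Other VGLL1 peaks of similar rank lacked a TEAD4 peak. At chromosome 1, 244882730 to 244883931, VGLL1 had a score of 5021, the second rank of its list, and the nearest TEAD4 midpoint in FULVR was 115 kb away. At chromosome 6, 27208901 to 27209807, the VGLL1 score was 4821 and that distance 53.9 kb. At chromosome 7, 67902815 to 67903675, the score was 4702 and the distance 39.0 kb. For the 10 strongest VGLL1 peaks without TEAD4 the distances ran from 2.25 kb to 945 kb, and 0 of the 10 carried an MCF7 TEAD4 peak. Over all VGLL1 peaks without FULVR TEAD4, 2.85% carried one.

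The last comparison set TEAD4 sites listed in both lines against those listed in FULVR alone by their VGLL1 overlap. Both classes carried VGLL1 at many sites, the shared class more often. VGLL1 overlapped 3270 of 5162 shared sites (63.3%, 95% interval 62.0 to 64.7) and 7237 of 15303 FULVR sites without an MCF7 peak (47.3%, 46.5 to 48.1). The odds ratio was 1.93 (two-sided Fisher's exact p = 1.75e-89, adjusted p = 1.4e-88). Shared sites were also the stronger ones, and within 5 classes of equal size by TEAD4 score the odds ratio was 1.10 (n = 20465 peaks, 95% interval 1.02 to 1.19, Cochran-Mantel-Haenszel p = 0.00894, adjusted p = 0.00894). Scores still varied within a class, from 253 to 3810 in the highest, so a remaining effect of score on this value stays open. With midpoints within 200 bp in place of overlap the odds ratio within classes was 1.03 (n = 20465 peaks, 0.957 to 1.11, Cochran-Mantel-Haenszel p = 0.43) and did not pass the test. Among the 20% of TEAD4 sites with the highest scores, 80.8% of 2198 shared and 81.4% of 1895 unshared sites carried VGLL1, an odds ratio of 0.963 (two-sided Fisher's exact p = 0.66, adjusted over the 5 classes p = 0.66). Among the 20% with the lowest scores the shares were 38.5% of 494 and 29.5% of 3599 (two-sided Fisher's exact test, adjusted p = 0.00037). The dense stretches move with this comparison: 42.5% of FULVR TEAD4 peaks inside them were shared with MCF7, against 24.5% outside, and 15.4% carried VGLL1, against 52.9% outside. Without them the odds ratio was 2.08, and 1.18 within score classes.

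**Figure D3:**
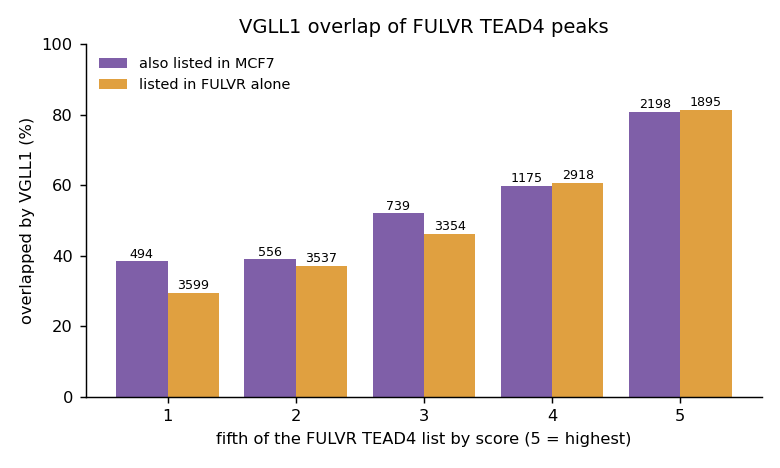
Percentage of FULVR TEAD4 peaks overlapped by a VGLL1 peak (y axis) in 5 classes of equal size by TEAD4 score (x axis, 5 = highest), for peaks also listed in MCF7 and peaks listed in FULVR alone, with the number of peaks above each bar. In the highest class the bars stand at 80.8% and 81.4%.

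VGLL1 overlap also differed among the TEAD4 sites of the parental line, a comparison added after the data were seen. VGLL1 peaks of FULVR cells overlapped 3249 of 5077 MCF7 TEAD4 sites that had a FULVR TEAD4 peak (64.0%, 62.7 to 65.3). They overlapped 574 of 1749 MCF7 sites that had none (32.8%, 30.7 to 35.1), an odds ratio of 3.64 (two-sided Fisher's exact p = 6.7e-114, outside the adjusted family). Of the VGLL1 peaks without FULVR TEAD4, 560 of 19651 (2.85%) overlapped an MCF7 TEAD4 peak. Of those with FULVR TEAD4, 3215 of 10279 (31.3%) did. The MCF7 sites with a FULVR TEAD4 peak are the shared sites compared above, counted on the MCF7 list. Their 64.0% therefore largely repeats the 63.3% given there. Both contrasts partly restate the overlap of FULVR TEAD4 with VGLL1 and with MCF7 TEAD4, where 74.4% of MCF7 peaks had a FULVR peak.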

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

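The window size, the merging rule and the tests in this part were chosen after the data were seen. In 9 of 595 windows of 5 Mb the share of the list's TEAD4 peaks differed between FULVR and MCF7 (Fisher's exact test, adjusted p under 0.05), and shares below are given as FULVR minus MCF7 in percentage points of each list. MCF7 had the larger share in 6 windows. These were chromosome 6, 25 to 30 Mb (-0.918), chromosome 20, 55 to 60 Mb (-0.727), chromosome 16, 0 to 5 Mb (-0.571), chromosome 1, 145 to 150 Mb (-0.517), chromosome 5, 175 to 180 Mb (-0.395) and chromosome 16, 85 to 90 Mb (-0.390). In each of them except chromosome 6, FULVR still held more peaks than MCF7, such as 256 against 135 on chromosome 20. Shares take no account of score, and the lists differ in length at unknown depth. A larger share in the shorter list therefore need not mean more binding in MCF7. FULVR had the larger share in 3 windows, chromosome 3, 60 to 65 Mb (0.425), chromosome 19, 30 to 35 Mb (0.186) and chromosome 18, 5 to 10 Mb (0.171). When peaks within 10 kb of each other were counted once, 3 windows passed, of which 1, on chromosome 18, was among the 9. The other 2 were chromosome 20, 45 to 50 Mb and 50 to 55 Mb, where MCF7 had the larger share after merging. At 45 to 50 Mb merging took FULVR from 548 to 109 peaks and MCF7 from 233 to 84. At 50 to 55 Mb it took them from 372 to 62 and from 100 to 51. Merging joins more peaks where a list is denser, and whether the rule alone gave these 2 calls was not tested. At 45 to 50 Mb the ratio of the FULVR to the MCF7 share went from 0.784 (95% interval 0.675 to 0.912) to 0.458 (0.345 to 0.608). At 50 to 55 Mb this ratio turned from 1.24 (0.997 to 1.54) to 0.429 (0.297 to 0.621). In 4 of the 8 windows that no longer passed, this ratio moved little, and the counts were smaller. It went from 7.34 (1.78 to 30.3) to 6.53 (1.58 to 27.1) on chromosome 19 and from 0.460 (0.320 to 0.662) to 0.439 (0.278 to 0.693) on chromosome 5. It went from 0.488 (0.360 to 0.662) to 0.543 (0.364 to 0.812) on chromosome 1 and from 0.524 (0.375 to 0.732) to 0.573 (0.381 to 0.862) on chromosome 16, 85 to 90 Mb. On chromosome 16, 0 to 5 Mb, it went from 0.473 (0.352 to 0.636) to 0.638 (0.436 to 0.933), and on chromosome 20, 55 to 60 Mb, from 0.633 (0.514 to 0.778) to 0.737 (0.493 to 1.10). On chromosome 3 it turned from 1.91 (1.31 to 2.77) to 0.883 (0.579 to 1.35). There merging took FULVR from 183 to 75 peaks and MCF7 from 32 to 30, so the same limit of the rule applies.

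On chromosome 6, 25 to 30 Mb, the MCF7 list held 92 TEAD4 peaks and the FULVR list, 3.00 times as long, 88. After merging, the counts were 36 and 48, the ratio of shares went from 0.319 (0.238 to 0.427) to 0.471 (0.306 to 0.725) and the adjusted p from 3.5e-11 to 0.124 (Fisher's exact test), so split peaks as part of the cause stay open. On chromosome 18, 5 to 10 Mb, FULVR had 35 TEAD4 peaks and MCF7 0, where 11.7 would match the list lengths. That value takes no account of score. Over the whole list, MCF7 overlapped 11.3% of the lowest-scoring 10% of FULVR peaks and 63.8% of the highest. The scores of the 35 peaks were not examined. Merging left 31 and 0 (Fisher's exact test, adjusted p = 0.0243), which argues against split peaks as the whole cause. A lower copy number of this window in MCF7 and a difference in TEAD4 binding between the lines or cultures stay open as untested, since input reads were not analysed here.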

How the results depend on the processing

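Removing dense clusters, merging neighbouring peaks, all settings of the odds ratio within score classes and 7 settings of the score comparisons were chosen after seeing the data; the other alternatives were planned. Of 53 recomputed values, 51 kept their direction and their side of the 0.05 threshold. The settings were overlap of at least 50% of the shorter peak, midpoints within 200 bp, the upper 50% of each list by score, lists of equal length, autosomes only and the removal of dense clusters for the 8 main tests, and uniform random placement for the overlap tests. The share of MCF7 TEAD4 peaks found in FULVR ranged from 44.8% with lists of equal length to 76.2% in the upper 50% of the lists. The share of FULVR TEAD4 peaks with VGLL1 ranged from 30.96% with lists of equal length to 52.9% without dense clusters. The share of FULVR TEAD4 peaks found in MCF7 ranged from 23.7% with midpoints within 200 bp to 44.5% with lists of equal length. The odds ratio of VGLL1 overlap between shared and unshared TEAD4 peaks ranged from 1.65 with lists of equal length to 2.08 without dense clusters. The odds ratio within score classes ranged from 1.03 with midpoints within 200 bp (n = 20465 peaks, p = 0.43), where it no longer passed the test and the cause was not tested, to 1.30 with lists of equal length. The other value that changed was the number of 5 Mb windows that differed between the TEAD4 lists, from 9 to 3 when peaks within 10 kb were counted once; the cause was not tested. No paired analysis was possible because the lists hold no replicate values, and for the same reason no replicate could be left out in turn. Other settings for gene locations, motifs and gene lists were not run, as those results were not computed. Depth is unknown for all 3 lists, so the absence of a peak is not evidence that a site was unbound.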

Other observations

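The values and tests in this part were chosen after the data were seen, except that the rotation within dense stretches and the share of TEAD4 scores under 40 were set before their results were known. VGLL1 peaks also lay in clusters, and the 5 with the most VGLL1 peaks all held FULVR TEAD4 peaks. Of all VGLL1 peaks 34.3% were overlapped by FULVR TEAD4, so clusters of many peaks would often hold some, and no test was made. The largest cluster, at chromosome 12, 52557771 to 52597593, held 17 VGLL1 peaks in 39.8 kb, together with 12 FULVR TEAD4 and 2 MCF7 TEAD4 peaks. A cluster at chromosome 3, 134069748 to 134101107, held 14 VGLL1, 12 FULVR TEAD4 and 7 MCF7 TEAD4 peaks. A cluster at chromosome 1, 151941456 to 151971808, held 12 VGLL1, 5 FULVR TEAD4 and 1 MCF7 TEAD4 peaks. A cluster at chromosome 17, 57906545 to 57935202, held 12 VGLL1, 10 FULVR TEAD4 and 10 MCF7 TEAD4 peaks and overlapped a dense TEAD4 stretch at 57910190 to 57982637. Most peaks stood alone: 58.6% of VGLL1, 61.3% of FULVR TEAD4 and 68.6% of MCF7 TEAD4 peaks had no neighbour of the same list within 10 kb.

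The parental TEAD4 sites without a FULVR TEAD4 peak carried VGLL1 less often in each of 5 classes of MCF7 score. In the highest-scoring 20% of the MCF7 list, 81.9% of 1324 sites with a FULVR TEAD4 peak carried VGLL1, against 24.4% of 41 sites without one. In the lowest 20% the shares were 50.6% of 697 and 32.3% of 669. The odds ratio within score classes was 2.59 (95% interval 2.30 to 2.93). Like the odds ratio without score classes, it partly restates the overlap of VGLL1 with FULVR TEAD4.

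Most dense TEAD4 stretches lay on chromosomes 17 and 20, on which MCF7 is known to carry amplified DNA; the values here cover all 16 stretches, with those on chromosomes 2 and 21. Peaks placed at random over raised background are argued against: 85.4% of MCF7 TEAD4 peaks in the stretches were overlapped by FULVR TEAD4, 1.73 times the 49.3% after rotation inside each stretch (permutation p = 0.001, the smallest possible). TEAD4 sites in the stretches carried VGLL1 less often than elsewhere, with an odds ratio of 0.198 within score classes (95% interval 0.160 to 0.245), which separates no explanation from another in stretches chosen on TEAD4 counts. A gain in depth from extra DNA copies stays open: VGLL1 peaks were 8.77 times as dense in the stretches as in the rest of the genome, and the ratio of this to the FULVR TEAD4 value of 76.9, 0.114, decides nothing for the same reason. Background that is uneven at the same positions in both lines, and TEAD4 binding without VGLL1, also stay open, since input reads were not analysed here.

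In the highest-scoring 10% of the VGLL1 list, 1375 peaks had no overlapping TEAD4 peak in FULVR. Midpoints just outside the overlap rule are argued against as the whole cause, since 1.24% of these peaks had a TEAD4 midpoint within 1 kb and the median distance was 42.3 kb. TEAD4 just under the threshold stays open: of the 1618 VGLL1 peaks of that class with TEAD4, 2.04% had a TEAD4 score under 40 (median 246). The test was set to count such a low share against this explanation, but it reaches only sites where TEAD4 was listed, and the 1375 sites have no TEAD4 score. Recruitment of VGLL1 by factors other than TEAD4, and recovery of other material by the VGLL1 antibody, could both leave such peaks, and neither was tested.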
